A study of Homo sapiens with 8 samples.

How the data were processed

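Total RNA of HepG2 and LM3 cells was depleted of ribosomal RNA, made into cDNA libraries and sequenced from both ends on an Illumina instrument, per the labels' protocols. The labels give 2 replicates for each of 4 groups, HepG2 with vehicle, HepG2 with JQ1, LM3 with vehicle and LM3 with JQ1. The values used here are FPKM that the authors deposited, per the file headers, in 1 table for each cell line, rounded to 2 decimals. Bowtie 0.12.2 and the builds hg19 and mm8 are named in the submitters' processing notes, without a role for any of them. The coordinates in the tables are nevertheless those of GRCh38. Of 14860 Ensembl IDs found in GENCODE release 29, 100% were on the same chromosome, 85.7% had the same start and 86.0% the same end, and all coordinates are given on GRCh38. The counting tool, its annotation and strand setting, the total behind the per-million scale and the origin of the LXLOC loci are not given in the sources used here.

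Each table lists the same 23161 loci, 16880 with an Ensembl ID and 6281 with an LXLOC name. A dash stood in place of all values for 7692 loci, which were left out, and 15469 remained. Symbols were found for 14896 Ensembl IDs, and 20 of these were protein coding. Of the loci with values, 2896 overlapped another on the same strand by at least 0.5 of the shorter, and 1439 LXLOC loci overlapped a coding gene on the same strand. Values of overlapping loci, of near-identical copies such as CYTOR and MIR4435-2HG, and of antisense loci are uncertain, because reads may have been split or counted more than once among them.

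Tests were made within a line's table, since the tables may have been normalized separately. JQ1 was compared with vehicle in limma 3.58.1 (R 4.3.3, moderated with trend and robust fitting) on log2(FPKM + 0.5), for loci with a mean of at least 0.5 FPKM over the 4 libraries of the line. The test was two-sided, with Benjamini-Hochberg adjustment over the loci tested and a threshold of 0.05. A fold change is thus on the log2(FPKM + 0.5) scale, which understates the change of low loci. The difference between the lines' responses was tested in 1 limma fit over all 8 libraries with a mean per group, for loci that passed the filter in both tables, so that a scale difference between tables cancels within each line. Overlaps of calls were tested with Fisher's exact test. Tables were prepared and plotted with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

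Lists of lncRNAs (13) and classes read from gene symbols (9) were fixed from general knowledge, as were the groups, tests, naming rule and alternatives, before the data were examined. Lists with at least 5 tested members were compared with the other loci by limma camera at a preset correlation of 0.01, and again with the correlation estimated, with adjustment over the lists or classes of a line. The fry test, run beside them, asks whether a list moves on balance 1 way and compares it with no other genes. Of the list members, 35 of 37 growth-promoting, 17 of 22 tumour-suppressive, 15 of 23 hepatocyte, 29 of 30 snoRNA host, 11 of 17 p53-responsive, 10 of 16 8q24, 21 of 25 super-enhancer, 16 of 21 nuclear, 10 of 18 imprinted, 17 of 20 HOX, 14 of 19 inflammatory, 11 of 16 hypoxia and 14 of 19 other-cell-type lncRNAs had values. Lists of coding genes could not be used, because none of their genes had values.

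Named genes were those called, with a symbol, a mean of at least 1 FPKM in the higher group and groups that did not overlap: the 8 largest rises and falls without a clone-based name, and the 4 most abundant in each direction, per line. From each list up to 4 called members with the smallest p were named, or 2 where none was called, and from the difference between lines the 4 with the smallest adjusted p in each direction. H19, and MALAT1 in HepG2, are given whether called or not. DUXAP8, the loci around RNU2-1 and those in the additional observations were chosen after their values were seen. Loci of a single line were those at a mean of at least 0.5 FPKM there and under 0.1 FPKM in the other, and medians were compared by a permutation test with 100000 draws.

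Low values were searched for the steps that whole fragments would leave, over loci of 200 to 400 bp. Between 28.0% and 37.6% of values per library lay within 0.1 of a whole number of steps, where evenly spread values would give 20%. The score of the best step, 0.207 to 0.372, was above the highest of 200 random draws in every library (0.194 to 0.292), but most values lay off whole steps, so fragment counts were not recovered, no count model was run, and the relative depths in the report are approximate. With FPKM alone, counting error per locus cannot be given, and the precision is that of the spread between libraries.

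The limma steps were tested on simulated data with 200 changed loci per line and independent normal errors. The changed share was far below the share called in the data (25.1% in HepG2 and 23.3% in LM3), so the recovery need not hold for these data. After simulation 5463 loci in HepG2 and 6063 in LM3 passed the filter, and the shares are over these. At an absolute log2 fold change of 1, 71.7% of changed loci were called with the right sign in HepG2 and 64.0% in LM3. For a change of 2 the shares were 86.7% and 84.1%, and 3 of 134 and 5 of 131 calls were of unchanged loci. For the difference between lines (4589 loci), 71.6% and 95.2% were called at a difference of 1 and 2, and 13 unchanged loci were called.

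Alternatives were a pseudocount of 0.1 or 1, no filter or a filter at 1 FPKM, quantile normalization, centring each library on its median, limma without trend or robust fitting, the replicate number as a block, leaving out each library in turn, a minimum absolute log2 fold change of 1, an unadjusted p under 0.01 for the overlap, and other settings of the list tests. Leaving out loci that overlap another, rescaling to the FPKM sum outside the 34 ribosomal RNA and mitochondrial loci, and taking the other line's level from its vehicle libraries were added after seeing the data.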

Results

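Long noncoding RNA levels were measured in HepG2 and LM3, 2 human hepatocellular carcinoma cell lines treated with JQ1 or with the DMSO vehicle. JQ1 is a small molecule that displaces BET bromodomain proteins from acetylated chromatin. Super-enhancers, the dense enhancer clusters named in the study's title, are known to be sensitive to such inhibitors, and the comparisons ask which lncRNAs responded in each line and whether the lines responded alike. The labels give 4 groups of 2 libraries each, 8 in all, with neither the dose of JQ1 nor the time of treatment. Libraries were made from total RNA after depletion of ribosomal RNA and sequenced in pairs of reads.

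Each line had its own table of FPKM values (fragments scaled to transcript length and library size) for the same 15469 loci with values. Of these, 9585 carried an Ensembl gene ID and 5884 a locus name of the authors' own that begins with LXLOC. The FPKM of all loci summed to 30699 and 29369 in the HepG2 vehicle libraries of replicates 1 and 2, and to 31309 and 32765 in the HepG2 JQ1 libraries. In LM3 the sums were 34066 and 35742 with vehicle and 34148 and 34771 with JQ1. Loci with a value above 0 numbered 12268, 12105, 11999 and 12062 in HepG2, in the same order of libraries, and 11866, 12332, 11230 and 11992 in LM3. Ribosomal RNA and mitochondrial loci held 15.3% and 15.9% of the FPKM in the HepG2 vehicle libraries and 17.1% and 18.1% in the JQ1 libraries. In LM3 these loci held 18.9% and 19.6% with vehicle and 21.2% and 22.8% with JQ1. Total read counts are not given in the sources used here. The spacing of low values gave an approximate depth relative to the mean of a table's libraries of 1.01, 0.872, 1.08 and 1.04 in HepG2 and of 0.980, 1.03, 0.750 and 1.24 in LM3, though at most 37.6% of the low values of a library lay near a whole step. Across genes, Pearson's r between replicates was 0.973 for vehicle and 0.979 for JQ1 in HepG2, and 0.976 and 0.961 in LM3. Values of r between a vehicle and a JQ1 library ran from 0.910 to 0.915 in HepG2 and from 0.896 to 0.911 in LM3. No label says that the replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

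In HepG2, LINC00910 (ENSG00000188825; chromosome 17, 43338741 to 43389199, minus strand of GRCh38) rose from 5.73 ± 0.354 to 52.4 ± 1.06 FPKM (mean ± SD, n = 2 per group, here and for all values that follow; log2 fold change 3.09, SE 0.076, adjusted p = 0.00144). NEAT1, the scaffold RNA of nuclear paraspeckles (chromosome 11, 65422774 to 65445540, plus strand), rose from 92.0 ± 4.53 to 182 ± 17.3 FPKM (log2 fold change 0.98, SE 0.10, adjusted p = 0.00864). CPS1-IT1 (chromosome 2, 210617571 to 210619876, plus strand), which lies within CPS1, a gene of the urea cycle, fell from 6.82 ± 0.0354 to 1.27 ± 0.0778 FPKM (log2 fold change -2.04, SE 0.082, adjusted p = 0.00262). LINC00963 (chromosome 9, 129476946 to 129513687, plus strand) fell from 20.6 ± 0.750 to 5.21 ± 0.332 FPKM (log2 fold change -1.89, SE 0.082, adjusted p = 0.00262), and FENDRR (chromosome 16, 86474529 to 86509099, minus strand), a neighbour of the transcription factor gene FOXF1, from 8.71 ± 0.601 to 2.79 ± 0.12 FPKM (log2 fold change -1.48, adjusted p = 0.00513).

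Further falls in HepG2 on the log2 scale were -1.64 for SNHG26, -1.58 for PRR7-AS1, -1.48 for NTRAS, -1.39 for LINC01182 and -1.38 for BACE1-AS, which is antisense to the beta-secretase gene. Further rises were 1.38 for CD27-AS1, 1.31 for NDUFA6-DT, 1.21 for EMC1-AS1, 1.15 for ADAMTSL4-AS1, 1.11 for LINC02804 and 1.01 for LINC00310. Among abundant lncRNAs, SNHG16 fell from 148 ± 3.005 to 114 ± 1.15 FPKM, MIR4435-2HG from 98.2 ± 1.31 to 69.4 ± 2.71 FPKM and SNHG17 from 82.0 ± 1.06 to 55.04 ± 0.849 FPKM. PVT1, a neighbour of MYC (chromosome 8, 127794526 to 128187101, plus strand), fell from 91.1 ± 1.97 to 56.5 ± 2.03 FPKM (log2 fold change -0.68, SE 0.070, adjusted p = 0.00873). IGFL2-AS1 rose from 36.2 ± 2.85 to 56.0 ± 2.01 FPKM, SNHG12 from 32.7 ± 1.00 to 43.2 ± 1.047 FPKM and AC245014.3, which overlaps the variant U1 gene RNVU1-14, from 18.5 ± 3.03 to 67.2 ± 0.460 FPKM. The most abundant of the lncRNAs in the gene lists passed no threshold in HepG2. H19, an imprinted RNA, was at 2143 ± 149 and 2168 ± 94.1 FPKM with vehicle and JQ1 (log2 fold change 0.017, adjusted p = 0.906), and MALAT1, an RNA of nuclear speckles, at 1647 ± 75.7 and 1760 ± 53.7 FPKM (0.10, adjusted p = 0.436).

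Of 5906 loci tested in HepG2 with limma, 1480 passed an adjusted p of 0.05, 640 higher and 840 lower with JQ1, and 2376 had an unadjusted p under 0.05. A change of at least 2-fold was seen for 89 of the higher and 160 of the lower loci. Loci with an Ensembl ID made up 156 of the rises and 294 of the falls, and the authors' own loci 484 and 546. The count of calls was 424 without vehicle replicate 1, 475 without vehicle replicate 2, and 0 by limma without either JQ1 library, where 1771 and 1679 loci had an unadjusted p under 0.05. The excess of falls depended on the scaling, with 809 loci higher and 786 lower when each library was centred on its median, 758 and 818 after quantile normalization, and 571 and 957 after rescaling to the sum outside ribosomal RNA and mitochondrial loci, a setting chosen after seeing the data. The balance also turned on single libraries. The median log2 fold change of the tested loci was -0.0056 with all libraries, 0.040 without vehicle replicate 1 and -0.052 without JQ1 replicate 2. Without the filter on low values the calls of CD27-AS1, SNHG12, MIR22HG, LINC01089, LINC01485, PURPL and HAGLROS were lost, as was that of HAGLROS with centred libraries and that of SNHG16 with replicates as blocks.

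Lists of lncRNAs fixed from general knowledge were then compared with the other loci in HepG2, and NEAT1 and PVT1 belonged to several of them. List members all have an Ensembl ID, while the other loci include LXLOC loci. Ensembl loci had a median log2 fold change of -0.052 against 0.024 for LXLOC loci in HepG2, and -0.155 against -0.045 in LM3. Part of a list's downward shift against the other loci may therefore be that of Ensembl loci as a whole. Of 15 measured lncRNAs described as super-enhancer-associated in any cancer or cell type, 8 fell, 2 rose and 5 were not called. Their median log2 fold change was -0.43 (limma camera adjusted p = 0.0602, and adjusted p = 0.745 with an estimated correlation). MIR17HG, the host of a microRNA cluster, fell from 8.46 ± 0.127 to 4.25 ± 0.141 FPKM and MIR100HG, another microRNA host, from 29.9 ± 1.87 to 16.02 ± 0.891 FPKM. HOX cluster lncRNAs included 2 of 10 that fell and none that rose (median -0.32; camera adjusted p = 0.0359, and adjusted p = 0.531 with an estimated correlation). HOXA10-AS fell from 1.36 ± 0.0778 to 0.605 ± 0.0354 FPKM and HAGLROS from 0.950 ± 0.0424 to 0.555 ± 0.0636 FPKM. Among 28 snoRNA host genes, which carry small nucleolar RNAs in their introns, 6 fell, 1 rose and 21 were not called (median -0.14; camera adjusted p = 0.0359, and adjusted p = 0.531 with an estimated correlation). SNHG26 fell from 12.5 ± 0.559 to 3.71 ± 0.587 FPKM, SNHG15 from 35.2 ± 1.75 to 23.0 ± 0.346 FPKM and SNHG4 from 36.7 ± 1.41 to 25.7 ± 1.46 FPKM. The medians of these lists stayed negative under every scaling tried. Camera called 2 lists in HepG2 at the preset correlation, but 1 with replicates as blocks.

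The other lists tested in HepG2 had higher camera p-values. Of 28 lncRNAs reported as growth-promoting in hepatocellular carcinoma, 6 fell and 2 rose (camera adjusted p = 0.596), with falls of LUCAT1 from 12.4 ± 0.750 to 7.45 ± 0.134 FPKM and of CYTOR from 74.7 ± 0.559 to 54.0 ± 3.24 FPKM. Of 5 reported as tumour-suppressive, 2 fell and 1 rose (adjusted p = 0.596), with FENDRR and LINC01089 (-0.42) lower and MIR22HG (0.59) higher. Among 7 p53-responsive lncRNAs, NEAT1, MIR22HG and PURPL, a p53-induced RNA (15.2 ± 0.0707 to 19.8 ± 0.389 FPKM), made 3 that rose, and PVT1 the 1 that fell (camera adjusted p = 0.717). Their median was -0.015, positive when each library was centred on its median and after quantile normalization, against a mean of 0.11. The nuclear and housekeeping RNAs had 2 that rose and 1 that fell among 16 (adjusted p = 0.717), with THUMPD3-AS1 at 0.66. For 5 inflammatory and interferon lncRNAs the counts were 1 higher and 2 lower (camera adjusted p = 0.596), with WAKMAR2 at -0.95, and adjusted over the list alone 3 were lower. Their median of -0.70 was the lowest of the lists tested in HepG2. The hypoxia list had 1 higher and 1 lower of 7 (adjusted p = 0.937), NEAT1 and LUCAT1. None of 5 imprinted lncRNAs was called by limma (adjusted p = 0.92; median 0.017, negative after rescaling without ribosomal RNA and mitochondrial loci, and mean -0.085), and the smallest p belonged to MEG8 (-0.56, unadjusted p = 0.0267) and KCNQ1OT1 (0.20, unadjusted p = 0.0675). Of 4 measured lncRNAs of the 8q24 region around MYC, 2 fell, PVT1 and CASC19 (35.8 ± 0.948 to 14.9 ± 1.74 FPKM). LINC01485 fell among 2 measured hepatocyte lncRNAs (0.960 ± 0.0283 to 0.370 ± 0.127 FPKM). FENDRR was the 1 that fell of 2 measured lncRNAs listed for other cell types. Counts adjusted over the list alone equalled those over all loci in the other lists that were tested.

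**Figure D1:**
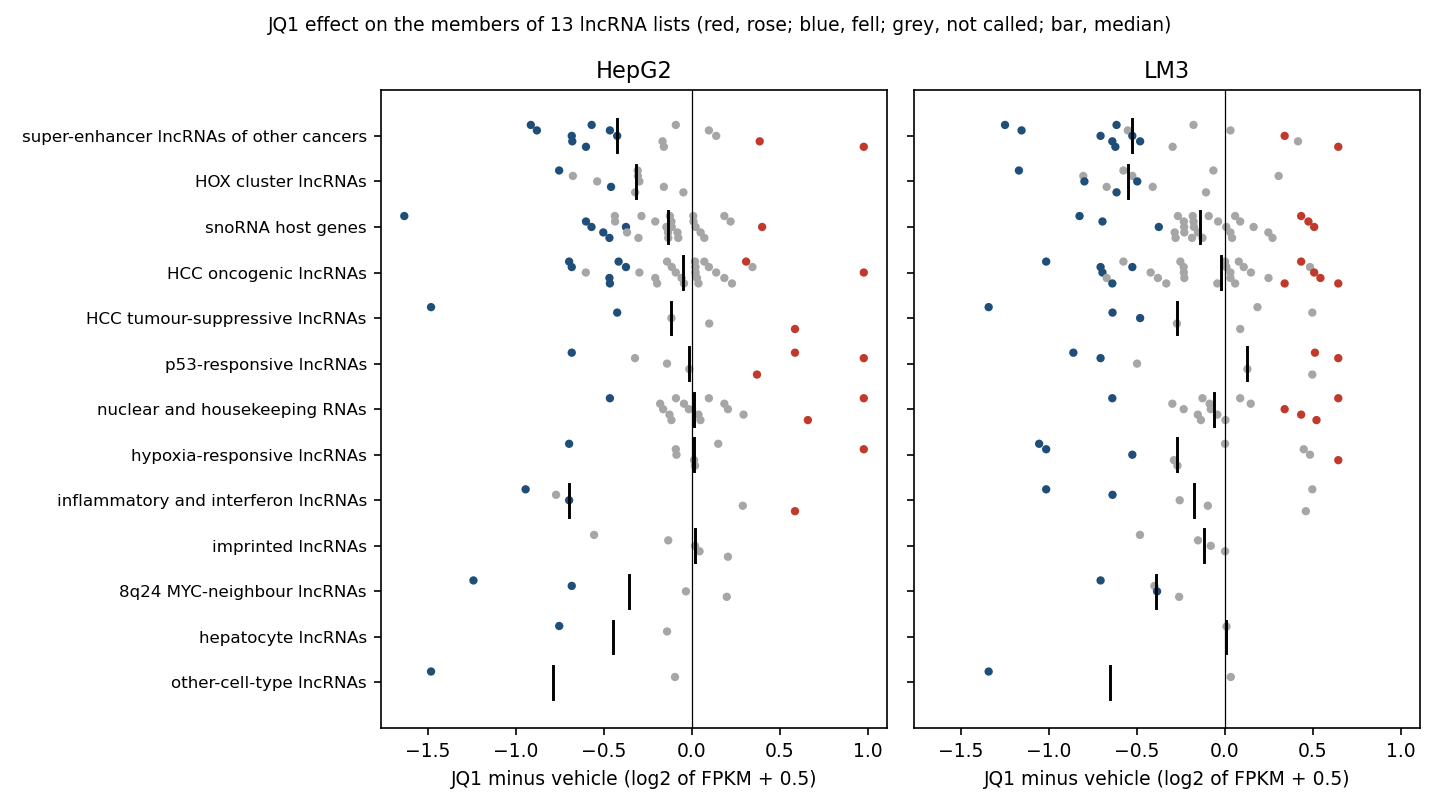
Log2 fold change of JQ1 minus vehicle, on log2(FPKM + 0.5), for each measured member of 13 lncRNA lists in HepG2 (left) and LM3 (right). Red points rose, blue points fell and grey points were not called by limma, and a black bar marks each list's median; the super-enhancer list had 8 members that fell and 2 that rose in each line.

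LM3 was tested in the same way. LINC00963 (chromosome 9, 129476946 to 129513687, plus strand) fell from 35.6 ± 0.735 to 6.83 ± 0.191 FPKM (log2 fold change -2.30, SE 0.080, adjusted p = 0.00443), and PAX8-AS1 (chromosome 2, 113211421 to 113276581, plus strand), antisense to the transcription factor gene PAX8, from 5.15 ± 0.339 to 0.870 ± 0.127 FPKM (log2 fold change -2.05, SE 0.11, adjusted p = 0.00533). LINC00910 rose in LM3 as well, from 4.87 ± 0.247 to 15.2 ± 0.339 FPKM (log2 fold change 1.55, SE 0.085, adjusted p = 0.00533). NEAT1 rose from 117 ± 2.67 to 183 ± 4.07 FPKM (log2 fold change 0.64, SE 0.077, adjusted p = 0.0122) and PVT1 fell from 83.0 ± 1.66 to 50.6 ± 0.205 FPKM (log2 fold change -0.71, SE 0.077, adjusted p = 0.011). MALAT1 rose from 1110 ± 9.12 to 1406 ± 92.5 FPKM (log2 fold change 0.34, SE 0.082, adjusted p = 0.0491), a call lost with a pseudocount of 1, with quantile normalization, without the filter on low values, with replicates as blocks and in limma without trend or robust fitting.

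Further falls in LM3 were -1.76 for LINC00670, -1.63 for SBF2-AS1, -1.55 for NTRAS, -1.53 for CEACAM16-AS1, -1.50 for the microRNA host MIR99AHG and -1.50 for LINC02747. Further rises were 1.53 for NUP50-DT, 1.27 for HNRNPD-DT, 1.03 for RPAP3-DT, 1.03 for CD27-AS1, 1.01 for ASB16-AS1, 1.01 for NUDT19-DT and 0.94 for FLJ20021. Of the abundant lncRNAs, CASC19 fell from 331 ± 13.7 to 253 ± 6.95 FPKM, SNHG17 from 122 ± 1.64 to 93.7 ± 0.849 FPKM and MIR4435-2HG from 109 ± 1.91 to 72.2 ± 3.84 FPKM. SNHG1 rose from 91.7 ± 2.44 to 124 ± 4.34 FPKM and SNHG7 from 59.3 ± 0.884 to 84.7 ± 5.47 FPKM. The calls of CASC19 and SNHG17 were lost with each library centred on its median and in limma without trend or robust fitting, and those of SNHG17 and SNHG1 after quantile normalization. The call of SNHG17 was also lost after rescaling without ribosomal RNA and mitochondrial loci, without overlapping loci and with replicates as blocks. H19 was at 329 ± 26.1 and 329 ± 27.1 FPKM with vehicle and JQ1 (log2 fold change 0.00084, adjusted p = 0.995).

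Of 6474 loci tested in LM3, limma called 1511 at an adjusted p of 0.05, 513 higher and 998 lower, and 2607 had an unadjusted p under 0.05. The rises were 34.0% of the calls, against 47.6% (700 higher, 770 lower) with each library centred on its median, 49.4% (715 higher, 732 lower) after quantile normalization and 41.8% (605 higher, 842 lower) after rescaling without ribosomal RNA and mitochondrial loci. A change of at least 2-fold was seen for 88 higher and 267 lower loci. Loci with an Ensembl ID accounted for 111 of the rises and 328 of the falls, and the authors' own loci for 402 and 670. Leaving out any single LM3 library left 0 calls in limma, with 1656 and 1525 loci at an unadjusted p under 0.05 without vehicle replicates 1 and 2, and 2244 and 2365 without JQ1 replicates 1 and 2. Without the filter on low values the calls of CD27-AS1, FLJ20021, CASC19, SNHG17, SNHG1, SNHG7, NKILA, LINC01089, HOXD-AS2, HOXC-AS3, UCA1, THUMPD3-AS1 and TP53TG1 were lost, besides that of MALAT1, and with replicates as blocks that of HOXC-AS3.

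The same lists were tested in LM3, and none passed in limma camera, with 2 of 9 under an unadjusted p of 0.05. Of 15 super-enhancer lncRNAs, 8 fell and 2 rose, and adjusted over the list alone 9 fell and 3 rose. Their median was -0.53 (camera adjusted p = 0.122, and adjusted p = 0.64 with an estimated correlation). MIR100HG fell from 38.9 ± 1.27 to 16.1 ± 1.32 FPKM and TM4SF1-AS1 from 1.66 ± 0.0283 to 0.470 ± 0.0424 FPKM. HOX cluster lncRNAs had 4 of 12 that fell, and adjusted over the list alone 6 fell and 1 rose (median -0.55; adjusted p = 0.122, and adjusted p = 0.64 with an estimated correlation). HOXA10-AS fell from 1.82 ± 0.0141 to 0.535 ± 0.134 FPKM, HOTAIRM1 from 16.2 ± 0.608 to 10.4 ± 0.212 FPKM, HOXC-AS3 from 1.76 ± 0.325 to 0.80 ± 0.198 FPKM and HOXD-AS2 from 1.99 ± 0.0636 to 1.26 ± 0.0848 FPKM. The medians of both lists stayed negative under every scaling tried.

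Among 30 growth-promoting lncRNAs of hepatocellular carcinoma in LM3, 5 rose and 5 fell, and adjusted over the list alone 7 fell (adjusted p = 0.983); LUCAT1 fell from 2.33 ± 0.0495 to 0.900 ± 0.141 FPKM and SNHG20 from 8.49 ± 0.226 to 5.05 ± 0.184 FPKM, while DUXAP8 rose from 21.3 ± 0.170 to 31.4 ± 3.02 FPKM. FENDRR, NKILA and LINC01089 were the 3 that fell of 7 tumour-suppressive lncRNAs (adjusted p = 0.903), FENDRR from 3.40 ± 0.0636 to 1.03 ± 0.0212 FPKM, and the call of LINC01089 was lost when centred or rescaled and with replicates as blocks. The snoRNA host genes split evenly, with 3 that rose and 3 that fell of 28 (adjusted p = 0.983); SNHG12 rose from 40.2 ± 1.07 to 56.0 ± 0.311 FPKM and SNHG26 fell from 25.9 ± 0.601 to 14.4 ± 0.757 FPKM. Of 16 nuclear and housekeeping RNAs, 4 rose and 1 fell, and adjusted over the list alone 2 fell (adjusted p = 0.903; median -0.062, positive when centred or rescaled, and mean 0.023); the rises were those of MALAT1, NEAT1, SNHG1 and THUMPD3-AS1, and CYTOR fell from 74.9 ± 2.56 to 47.9 ± 2.21 FPKM. The p53-responsive lncRNAs had 2 that rose and 2 that fell of 7, and 3 each adjusted over the list alone (adjusted p = 0.903; median 0.13, mean -0.041); TP53TG1 rose from 1.22 ± 0.0636 to 1.95 ± 0.0778 FPKM and MIR34AHG, the host of a p53-induced microRNA, fell from 1.67 ± 0.0707 to 0.700 ± 0.170 FPKM. The hypoxia list had 1 higher and 3 lower of 9 (adjusted p = 0.903), with LINC01116 at -1.06 and UCA1 at -0.53. LUCAT1 and NKILA (-0.64) were the 2 that fell of 6 inflammatory and interferon lncRNAs (adjusted p = 0.904). In the 8q24 list PVT1 and CASC19 were the 2 that fell of 4, and FENDRR was the 1 that fell of 2 lncRNAs of other cell types. None of 4 measured imprinted lncRNAs was called by limma, with MEG8 at -0.48 (unadjusted p = 0.0385) and SNHG14 at -0.15 (unadjusted p = 0.171). The 1 measured hepatocyte lncRNA was matched to HULC through an Ensembl ID whose locus spans a broad interval (chromosome 6, 8435568 to 9294133, plus strand), so its value may hold other transcripts; it was at 0.555 ± 0.0778 and 0.560 ± 0.0283 FPKM with vehicle and JQ1 (unadjusted p = 0.952). Where no count adjusted over the list alone is given for a tested list, it equalled that over all loci.

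**Figure D2:**
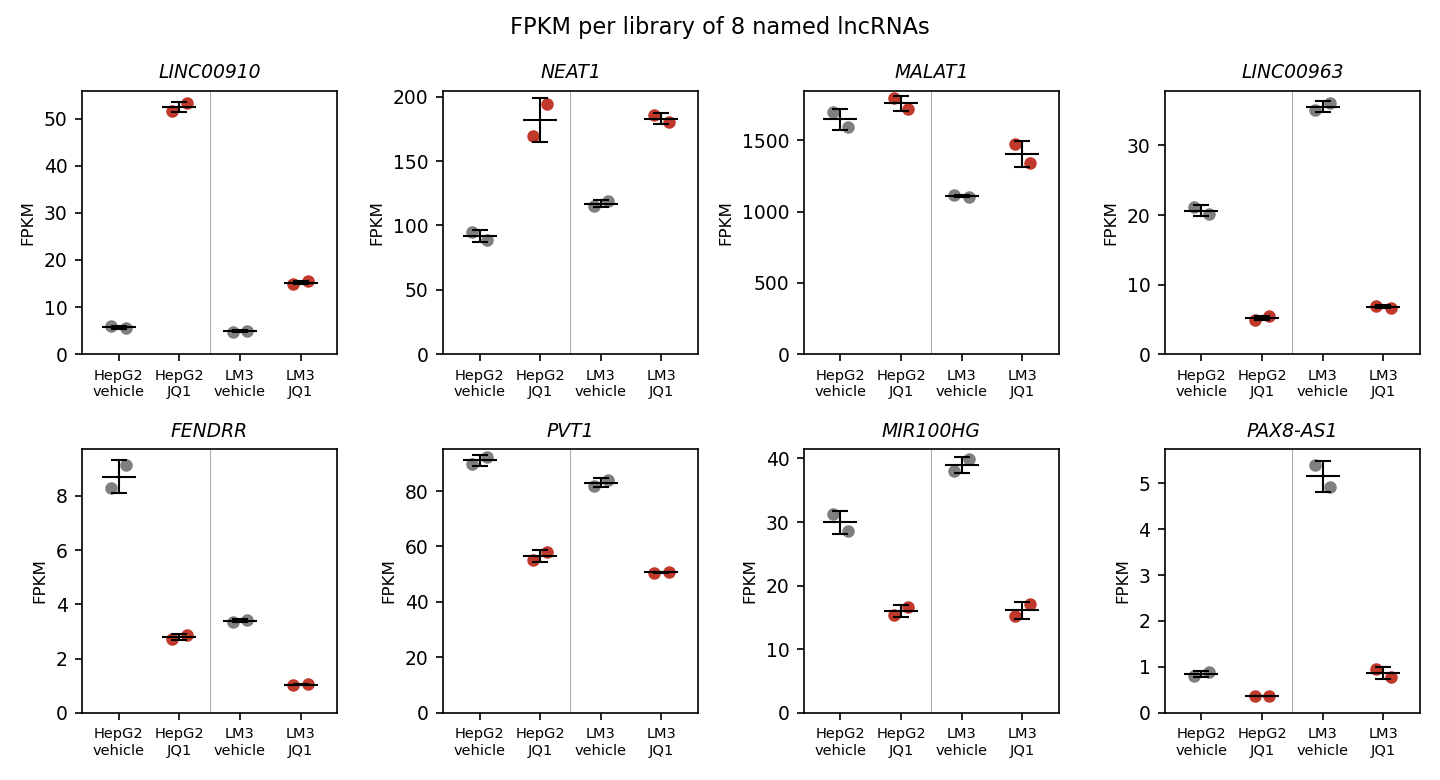
FPKM of 8 named lncRNAs in each library, by cell line and treatment, with vehicle in grey and JQ1 in red. Points are libraries, and bars show the mean and SD (n = 2); LINC00910 reached 52.4 FPKM in HepG2 and 15.2 in LM3 with JQ1, and levels are not comparable between the lines because the tables may have been normalized separately.

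The responses of the lines were compared across the 5035 loci tested in both, for which the comparisons shared no control libraries. LINC00910, NEAT1 and CD27-AS1 rose and LINC00963, FENDRR, NTRAS, MIR100HG, LUCAT1 and PVT1 fell in both lines. The 2 lines had 272 rises in common, from 546 in HepG2 and 420 in LM3, against 45.5 for independent lists (odds ratio 29.1, 95% interval 22.9 to 37.1, two-sided Fisher's exact p = 9.93e-183). They had 438 falls in common, from 644 and 676, against 86.5 (odds ratio 37.0, 95% interval 29.9 to 46.1, two-sided Fisher's exact p = 2.66e-287). Fisher's test treats loci as independent, although some overlap and may share reads. Its p-values are therefore likely too small and its intervals too narrow, and neither measures spread between replicates. Of 712 loci called in both lines, 710 had the same sign. Across genes, which are not independent replicates, the fold changes had a Pearson's r of 0.770 and a Spearman's rho of 0.733, and 76.6% had the same sign.

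**Figure D3:**
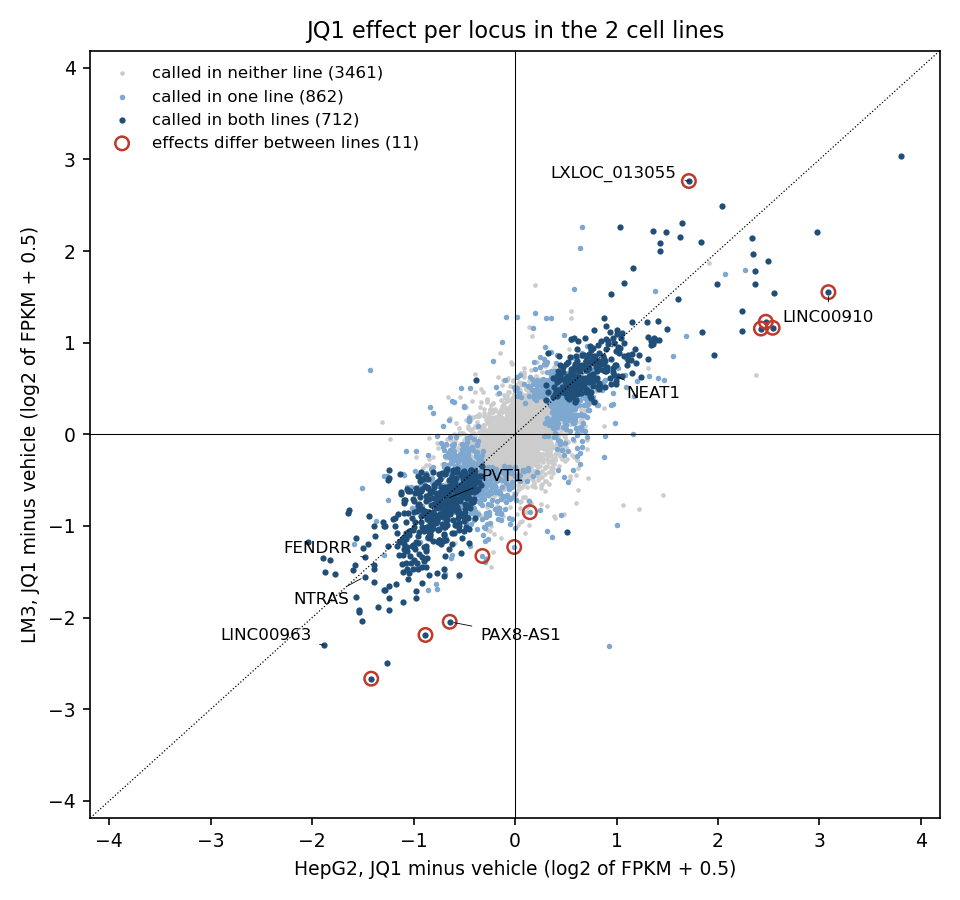
Log2 fold change of JQ1 minus vehicle in HepG2 (horizontal) and LM3 (vertical), on log2(FPKM + 0.5), for each of the 5035 loci tested in both. Grey points were called in neither line (3461), light blue in one (862) and dark blue in both (712), and red rings mark the 11 loci whose effects differed between the lines.

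A test of the difference between the lines' responses called 11 of the 5035 loci in limma, 10 with a lower effect in LM3 and 1 with a higher effect, and 604 had an unadjusted p under 0.05. LINC00910 rose less in LM3 (log2 difference -1.54, SE 0.11, adjusted p = 0.00938), as did LXLOC_024647 (-1.38, SE 0.096, adjusted p = 0.00938), which overlaps the U2 small nuclear RNA gene RNU2-1. LXLOC_030447, which overlaps PAX8-AS1, fell more in LM3 (-0.88 in HepG2, -2.19 in LM3; adjusted p = 0.0145), as did LXLOC_019865 (-1.42 and -2.67; adjusted p = 0.0145), which lies opposite IGF1R on chromosome 15. LXLOC_013055 (chromosome 12, 37237525 to 37240154, minus strand) rose more in LM3, by 2.76 against 1.71 (adjusted p = 0.028). Limma called 0 loci without any single library except LM3 JQ1 replicate 2, whose removal left 3, with 427 to 616 loci at an unadjusted p under 0.05 where none was called, and the calls were 94 without the filter on low values (67 lower and 27 higher in LM3), 20 with each library centred on its median (14 lower and 6 higher), 7 with a pseudocount of 0.1 (6 lower and 1 higher) and 19 with a pseudocount of 1 (16 lower and 3 higher). With replicates as blocks limma called 0, with 505 at an unadjusted p under 0.05.

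Several of these loci lay in 1 stretch of chromosome 17. Between 43.22 and 43.40 Mb, around RNU2-1, 8 loci were tested, 7 of them on the minus strand. In HepG2 all 8 rose, from 1.35 for LXLOC_024651 to 3.81 for LXLOC_024665. In LM3 7 rose, with 3.03 for LXLOC_024665 and 1.54 for LXLOC_023196 on the plus strand, and LXLOC_024650 was not called (1.07, adjusted p = 0.0788). LINC00910 and LXLOC_024665 overlap on the minus strand, where LXLOC_024650 and LXLOC_024651 also lie within LXLOC_024649. The counting at overlapping loci is not given in the sources used here, so the values of these overlapping loci are not independent.

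**Figure D4:**
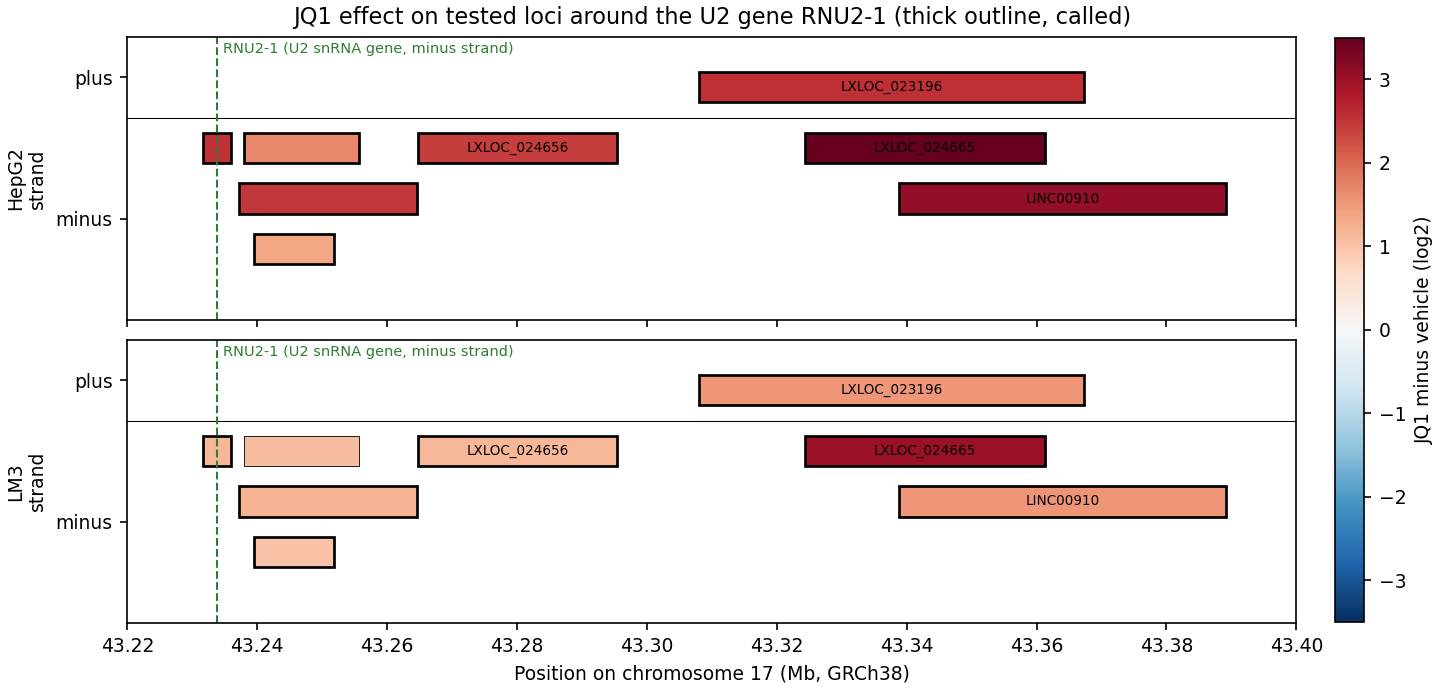
Tested loci on chromosome 17 between 43.22 and 43.40 Mb (GRCh38) in HepG2 (top) and LM3 (bottom), drawn to scale by strand and coloured by the log2 fold change of JQ1 minus vehicle, with a thick outline where called. The dashed line marks RNU2-1; all 8 loci rose in HepG2 and 7 in LM3.

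Loci expressed in one line alone fell more than loci expressed in both. Of 272 loci at a mean of at least 0.5 FPKM in HepG2 and under 0.1 in LM3, 38.2% fell and 4.78% rose, with a median log2 fold change of -0.32, against 12.8%, 10.8% and a median of 0.0088 for the 5035 loci in both (difference -0.33; two-sided permutation test across genes, p = 1e-05, the smallest that 100000 draws can give). Of 286 loci at that level in LM3 and under 0.1 FPKM in HepG2, 36.7% fell and 7.69% rose, with a median of -0.38, against 13.4%, 8.34% and -0.070 (difference -0.31; permutation p = 1e-05, also the smallest possible). Genes are not independent replicates, and the levels that define these loci come from tables that may have been normalized separately. When the other line's level was taken from its vehicle libraries alone, a definition chosen after seeing the data, the difference was -0.25 in HepG2 and -0.12 in LM3. By quartile of the mean level, from low to high, the medians were -0.0066, -0.013, -0.017 and 0.0099 in HepG2 and -0.069, -0.068, -0.11 and -0.096 in LM3.

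Classes read from the gene symbols were compared in the same way as the lists, and none passed in limma camera, with 2 in each line at an unadjusted p under 0.05. Like the lists, the classes hold Ensembl loci alone, which as a whole lay lower than LXLOC loci. Of 349 antisense lncRNAs tested in HepG2, 68 fell and 21 rose (camera adjusted p = 0.0696), and in LM3 73 of 347 fell and 9 rose (adjusted p = 0.111). Intergenic LINC genes had 40 falls and 22 rises among 197 in HepG2 (adjusted p = 0.237) and 48 falls and 17 rises among 229 in LM3 (adjusted p = 0.145). Divergent transcripts had 26 falls and 7 rises of 171 in HepG2 (adjusted p = 0.257) and 31 falls and 10 rises of 177 in LM3 (adjusted p = 0.747). For microRNA hosts the counts were 7 falls and 2 rises of 27 in HepG2 (adjusted p = 0.225) and 5 falls and 1 rise of 28 in LM3 (adjusted p = 0.269). SNHG genes had 6 falls and 1 rise of 25 in HepG2 (adjusted p = 0.0696) and 3 of each among 24 in LM3 (adjusted p = 0.754). Intronic transcripts had 4 falls and 1 rise of 32 in HepG2 (adjusted p = 0.766) and 2 falls and 1 rise of 32 in LM3 (adjusted p = 0.269). Overlapping transcripts, tested in HepG2, had 1 rise of 5 (adjusted p = 0.848). Loci with clone-based names had 89 falls and 82 rises of 834 in HepG2 (adjusted p = 0.972) and 120 falls and 56 rises of 928 in LM3 (adjusted p = 0.747). Adjusted over the class alone, the counts of falls and rises were 42 and 23 in HepG2 and 53 and 23 in LM3 for LINC genes, and 79 and 68 in HepG2 and 97 and 49 in LM3 for clone-based names. They were 24 and 6 in HepG2 and 34 and 10 in LM3 for divergent transcripts, 73 and 11 for antisense lncRNAs in LM3, and in HepG2 1 and 0 for intronic and 1 and 2 for overlapping transcripts. Strand use in the counting is not given in the sources used here, so an antisense locus and its coding partner may share reads.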

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

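The 11 loci listed here stood out because their response to JQ1 differed between HepG2 and LM3 in the planned limma test of that difference; no test in this part was chosen after its result was seen. Each value is the log2 fold change in LM3 minus that in HepG2, with the adjusted p of the difference and n = 2 libraries per group. Without any single library except LM3 JQ1 replicate 2 limma called 0 loci, where 427 to 616 loci had an unadjusted p under 0.05, and without that library it called 3 loci, 2 of them among the 11. With replicates as blocks limma called 0 loci, and 505 had an unadjusted p under 0.05.

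Around the U2 gene RNU2-1 on chromosome 17, the rise was smaller in LM3 for LINC00910 (-1.54; 3.09 in HepG2, 1.55 in LM3; adjusted p = 0.00938), LXLOC_024647 (-1.38; 2.54 and 1.16; adjusted p = 0.00938), LXLOC_024656 (-1.27; 2.42 and 1.15; adjusted p = 0.0187) and LXLOC_024649 (-1.24; 2.47 and 1.23; adjusted p = 0.0265). LXLOC_013055 on chromosome 12 was the 1 locus with the larger value in LM3 (1.05; 1.71 and 2.76; adjusted p = 0.028).

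The fall was steeper in LM3 for PAX8-AS1 (-1.40; -0.64 in HepG2, -2.05 in LM3; adjusted p = 0.0234), for LXLOC_030447, which overlaps PAX8-AS1 (-1.31; -0.88 and -2.19; adjusted p = 0.0145), and for LXLOC_019865 (-1.25; -1.42 and -2.67; adjusted p = 0.0145). LXLOC_034140 (chromosome 20, 53265132 to 53323540, plus strand) fell in LM3 and was not called in HepG2 (-1.22; -0.0087 and -1.23; adjusted p = 0.0234). LXLOC_049444 (chromosome 7, 25047050 to 25063726, plus strand) gave -1.01 (-0.32 and -1.33; adjusted p = 0.0439). RPL26L1-AS1 gave -0.996 (0.15 and -0.85; adjusted p = 0.028).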

How the results depend on the processing

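Leaving out overlapping loci, rescaling without ribosomal RNA and mitochondrial loci, and the other line's level from vehicle libraries alone were tests chosen after the data were seen; the first 2, run for the calls of each line alone, kept their total within 1.5 times its value as reported (falls without overlapping loci numbered 547 against 840 in HepG2 and 651 against 998 in LM3), and the third kept the differences between one-line and shared loci negative. Calls in HepG2 (1480) numbered 852 without the filter and 975 with a filter at 1 FPKM, where more and fewer loci were tested, 249 with a minimum absolute log2 fold change of 1, and 0 to 475 without 1 library. Calls in LM3 (1511) numbered 857 without the filter, 355 with the fold minimum and 0 (range 0 to 0) without 1 library. A fit with 3 libraries assumes that the lone library varies like the other group, and has 1 fewer sample to estimate the spread. Loci whose response differed between lines (11) numbered 7 and 19 with pseudocounts of 0.1 and 1, 94 without the filter, 20 with centred libraries and 0 to 3 without 1 library; the cause was not tested. Shared falls (438) numbered 291 with a filter at 1 FPKM, which left fewer loci. Lists called in HepG2 (2) numbered 0 with an estimated correlation and 6 by fry, and in LM3 (0 by camera, 2 of 9 at an unadjusted p under 0.05) 6 by fry, which asks another question than camera.

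Groups shared replicate numbers, but the labels do not say that a number marks a shared culture or day. Deviations of libraries with the same number correlated across genes by -0.0345 in HepG2 and 0.135 in LM3. With 2 libraries per group the deviations of replicate 2 mirror those of replicate 1, so each line gives 1 independent pair. With a replicate block, limma called 1453 loci in HepG2 and 1215 in LM3, 0 loci for the difference between the lines (505 at an unadjusted p under 0.05) and 1 list in HepG2; the cause was not tested.

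Of 1336 values of named genes under the alternatives, 955 stayed on their side of the threshold and 381 were no longer called. Among genes called as reported 0 values changed sign, and changes of sign among named genes that were not called were not counted. The calls lost were 89 each without JQ1 replicates 1 and 2, 61 and 58 without vehicle replicates 1 and 2, 44 under the fold minimum and 21 without the filter. Depth limits low loci most, and it cannot be given per locus because the values are FPKM.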

Other observations

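Several tests and definitions in this part were chosen after the result was seen. They include the definition of loci downstream of small RNA and histone genes, with its test of transcription past the 3' end, and the restriction to genes under 1 kb. The tests of ribosomal RNA carry-over and of shared reads beside histone genes, and the comparison of downstream with upstream loci, are others. So are the centring test of the LM3 split and the tests with the other line's level from vehicle libraries alone. The comparison of the authors' own loci with Ensembl loci was also made then. The remaining tests in this part had their bounds set before their results were seen.

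Loci downstream of small nuclear RNA, small nucleolar RNA and histone genes, placed by their annotated intervals, were mostly higher with JQ1. Taking 36 small RNA genes and 71 histone genes, 25 of the latter annotated at 1 kb or more and so not as a short transcript alone, 24 loci tested in HepG2 overlapped the 10 kb downstream of such a gene on its strand, of which 21 rose and 1 fell. In LM3 the numbers were 21 loci, 15 that rose and 1 that fell. LXLOC_047960, beside the histone gene HIST1H2BJ (chromosome 6, 27123493 to 27123883, minus strand), had log2 fold changes of 2.04 in HepG2 and 2.50 in LM3, AL021807.1, beside the same gene, 2.33 and 2.14, and LXLOC_046445, beside HIST1H2BO, 1.43 and 2.09. LXLOC_013953, which overlaps the U4 gene RNU4-2 and extends downstream of it, had 1.83 and 2.10. The exception that fell was LINC00623, which overlaps RNVU1-4 (-0.83 and -1.001). Loci that begin downstream of other coding genes had 119 rises and 114 falls among 965 in HepG2 (median 0.048) and 104 and 102 among 1122 in LM3 (median 0.032). All tested loci had 640 rises and 840 falls in HepG2 (median -0.0056) and 513 and 998 in LM3 (median -0.084). Loci downstream of other coding genes thus leaned less to falls than all tested loci.

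The downstream loci had a median of 1.31 in HepG2 and 1.01 in LM3, above the highest of 10000 level-matched draws (0.33 and 0.36). These loci were defined after their values were seen, and several lie beside the same gene while the draws took loci singly. Clearing the draws, here and for the subsets below, is therefore not independent support. Downstream of genes annotated at under 1 kb, which leaves out HIST1H2BJ, the median was 1.34 over 19 loci in HepG2 (16 rose, highest draw 0.46). In LM3 it was 1.01 over 17 loci (12 rose, highest draw 0.40). Beside histone genes lay 4 and 3 of these loci, all of which rose, among them AC239868.1. This locus also begins beside the 5' end of HIST2H4B on the opposite strand, so its placing downstream of the listed genes is ambiguous. Loci that lay only upstream of such genes had medians of 0.051 over 9 in HepG2, of which 3 rose, and 0.34 over 8 in LM3, of which 2 rose (two-sided Fisher's exact p against the downstream loci 0.00467 and 0.0382, across neighbouring loci that are not independent). Their upper quartiles (1.35 and 1.04) lay inside the range of the downstream loci, and those that rose all lay upstream of RNU2-1, with 2.47 for LXLOC_024649, 1.69 for LXLOC_024650 and 1.35 for LXLOC_024651 in HepG2, which transcription past the 3' end of RNU2-1 does not account for. LXLOC_024650 and LXLOC_024651 lie within LXLOC_024649, so these rises are not independent. Reads of the listed genes themselves are argued against for the downstream loci that do not overlap them. Those loci had a median of 1.29 over 13 loci in HepG2 (all rose, highest draw 0.63) and 1.13 over 10 in LM3 (9 rose, highest draw 0.52), and most of them lay beside histone genes. Most loci downstream of small RNA genes overlap the small RNA gene, and for them such reads stay open. Carry-over of structured RNA stays open. Ribosomal RNA arrays had medians of 0.22 and 0.21 and upper quartiles of 0.448 and 0.488, below the lower quartiles of the downstream loci (0.82 and 0.52). This argues only against a carry-over that raised both alike. The array medians still lay above those of all tested loci (-0.0056 and -0.084), and ribosomal RNA was depleted, so the arrays do not bound the carry-over of other RNA. Reads shared among copies of small nuclear RNA genes are argued against beside histone genes, where loci that hold no such copy had medians of 0.94 over 9 loci in HepG2 (all rose; highest draw 0.59) and 0.995 over 7 in LM3 (6 rose; highest draw 0.60). Beside small RNA genes such reads stay open in both lines. In LM3, 12 loci elsewhere with a small nuclear RNA pseudogene had a median of -0.15 and an upper quartile of 0.450, and 3 of them rose and 3 fell. In HepG2, 10 such loci went both ways (median 0.075, quartiles -0.456 and 1.25). These loci cannot decide, because the rest of a locus may hide shared reads at its pseudogene. A candidate explanation, as a hypothesis, is that with JQ1 more transcription continued past the 3' ends of the genes under 1 kb, RNU2-1 set apart. More transcription of the genes themselves also stays open, since their own RNA was not analysed here, and opposite-strand loci (medians -0.13 over 4 and -0.17 over 2) are too few to settle the strand.

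Loci expressed in 1 line fell more than loci expressed in both, by -0.33 in HepG2 and -0.31 in LM3. Choosing them on the JQ1 libraries of the other line leaves out loci that JQ1 raised there, and with its vehicle libraries alone the differences were -0.25 (permutation p = 0.0001, the smallest possible) and -0.12 (p = 0.0003), so this choice may account for part of the pattern, and in LM3 for more than it left. A lower level as the whole cause is argued against by level-matched draws of shared loci, whose lowest medians were -0.085 and -0.19 against -0.32 and -0.38, and, with vehicle libraries alone, -0.118 and -0.210 against -0.257 and -0.223. Overlapping loci as the whole cause are argued against, since leaving them out gave -0.38 in HepG2 and -0.28 in LM3 (permutation p = 0.0001 each, the smallest possible), and with vehicle libraries alone -0.31 (permutation p = 0.0001, also the smallest) and -0.11 (permutation p = 0.0011). The larger share of the authors' own loci among the one-line loci (81.2% and 86.0% against 67.2%) is argued against as the cause. Over all tested loci the authors' loci lay higher than Ensembl loci, with medians of 0.024 against -0.052 in HepG2 and -0.045 against -0.155 in LM3. A larger share of them would thus raise the one-line median. Whether Ensembl loci alone hold the pattern stays open. Their differences were -0.21 (51 loci, permutation p = 0.0008) and -0.34 (40 loci, permutation p = 0.0001). With vehicle libraries alone they were -0.096 (50 loci, permutation p = 0.104) and -0.072 (50 loci, permutation p = 0.301). No biological explanation was tested.

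In LM3 falls outnumbered rises, with 34.0% of calls higher, and 37.0% of loci at an unadjusted p under 0.05 in limma with all libraries. Uneven depth of the JQ1 libraries is argued against, as 31.5% of loci at an unadjusted p under 0.05 were higher without JQ1 replicate 1 and 35.6% without JQ1 replicate 2. Centring each library on its median gave 47.6% higher, but such centring balances rises and falls whatever the cause. A scaling difference between libraries and a net fall of the measured RNA therefore cannot be told apart, and no spike-in values were analysed here.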
